A study of Mus musculus with 36 samples.

How the data were processed

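Messenger RNA was measured in 18 RNA samples of mouse embryonic stem cells with an Oct4 reporter, each on 2 array types, so that each type holds 18 arrays. Per the labels' protocols, control cells grew in 1000 U per mL LIF and were collected 2 days after plating on gelatin, the other cells lost LIF or lost LIF and received RA, all were sorted by reporter fluorescence, and total RNA was amplified in 2 rounds before labelling. Sample groups were the 6 arms (control, days 1, 3 and 5 without LIF, days 1 and 2 with RA) and the 3 Oct4 gates (high, medium, low), read from the labels.

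The deposited tables hold signal intensities per probe set, made by the authors with MAS5, per the submitters' processing notes (the version is not given in the sources used here). The values are linear and above 0, and their trimmed mean, with 2% taken off each side, is 150.1 on every array of chip A to within rounding and 150.04 on every array of chip B, so the deposited values had been scaled within each array and were used without further normalization. Detection calls were not analysed here. The scan day of each array was read from the run records that accompany the arrays and used only to number 4 scan days. Gene symbols came from the platform annotation, checked against a table of mouse RefSeq genes of assembly GRCm38.p6 by Entrez identifier, and no coordinates were used. Of 12422 probe sets on chip A that are not controls, 10833 had 1 symbol, 396 had several and 1193 had none or were missing from the annotation. On chip B these were 12411, 10581, 178 and 1652. No probe set is annotated to T in that table, so this gene could not be followed, and Esrrb, Fgf5, Cdx2 and Rarb fell under the brightness filter.

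All computing was done in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Values were log2 transformed after adding a pseudocount of 4 on chip A and 7 on chip B, 0.1 of the chip's median rounded. Per chip, the 60% of probe sets with the highest mean log2 value were tested, 7453 on chip A and 7447 on chip B, 14900 in all. A linear model with additive terms for arm and gate was fitted to all 18 samples of each chip with limma (lmFit and eBayes), p-values were adjusted by the Benjamini-Hochberg method within each chip, and an adjusted p under 0.05 counts as past the test. The comparisons were days 1, 3 and 5 without LIF against control, days 1 and 2 with RA against control, day 1 with RA against day 1 without LIF, and the gates against each other. The slope per day and the low minus high difference in slope used the 13 samples of control (as day 0) and days 1, 3 and 5. The high gate at day 1 without LIF was compared with control high on its own 4 samples. Comparisons against control share the control libraries and so their chance values.

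Gene-level results use 1 probe set per gene among those with 1 symbol that pass the filter, chip A before chip B and then the brightest, which gives 9833 genes. The 17 lists were pluripotency network, LIF and STAT3 targets and receptors, retinoic acid response, Hox cluster genes, primitive streak and early mesoderm, extraembryonic endoderm, postimplantation epiblast, neural progenitors, trophoblast, fibroblast feeder markers, blood and endothelium, proliferation, cyclins D and CDK inhibitors, Polycomb and DNA methylation, dissociation and sorting stress, p53 targets, and glycolysis. They hold 315 distinct genes, 215 of them measured. Each was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 68 tests (17 lists in 4 comparisons), of which 25 passed, and again with an estimated correlation, with which 0 passed, so the list calls rest on the preset. For each list the members past the test over all probe sets were counted, and also those past it when adjusted over the list alone. The test sets a list against all other measured genes, not against no change, and weighs genes by their error. In 5 cases its direction differs from the sign of the list's median or mean, and none of these passed. They were RA response at day 5 (median 0.13, mean 0.31, test lower), and epiblast (0.19, 0.01, lower) and stress (-0.03, 0.01, lower) at day 1 with RA. Between the gates they were cyclins D and CDK inhibitors (-0.02, 0.07, higher) and glycolysis (0.02, 0.00143, lower).

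Genes are named by a rule. It takes the 8 largest rises and the 8 largest falls past the test in each of 4 main comparisons (day 5 without LIF and day 2 with RA against control, day 1 with RA against day 1 without LIF, low against high gate), the up to 4 members of each list with the smallest p there, and Pou5f1, Nanog, Sox2, Zfp42, Klf4, Gata6, Sox1, Cyp26a1 and Socs3. Genes named so are also given for other comparisons, and any other gene is said to be chosen after its values were seen. The grouping, tests, lists, filter, naming rule and the other settings listed below were set before the data were examined. Values after ± are standard errors of the fitted change unless SD is written.

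RNA quality was taken as the log2 ratio of 3' to 5' control probe sets of Gapdh and Actb on each array, compared between control and all other libraries by an exact permutation test over all 816 ways to choose 3 of 18. The fits were repeated with a pseudocount of 0.1 and of 4 times the value given, no filter, the brightest 30%, quantile normalization, a trended and robust variance, scan day as a fixed block, only the samples compared, the replicate number as a block, an estimated correlation or the median over probe sets for lists, and each sample left out in turn. Added after the data were seen were scan day as a random block (duplicateCorrelation), dropping the library labelled day 1 without LIF, high gate, replicate 2 (called the doubted library below), both together, and fits within scan 2 and within scan 3. The 40 genes used to place that library were called in both within-scan comparisons of RA with no RA, neither of which contains it.

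The code was tested on simulated data for the same design with 100 probe sets changed 2-fold and 100 changed 4-fold among 14900. Simulated values varied independently, with no scan day effect and no change besides those added. The numbers recovered therefore do not cover the mixing of arm with scan day in the real data. At day 5 without LIF against control it recovered 57 and 91 of them, at day 1 with RA against day 1 without LIF 70 and 95, at day 2 with RA against control 47 and 83, and between low and high gates 82 and 99. Of 100 simulated lists the 1 that was shifted passed camera (adjusted p = 1.96e-42, and 9.14e-06 with an estimated correlation), and 0 of the 99 others did. The simulated lists were not matched to the real ones in correlation between genes, which was estimated at 0.443 for the pluripotency network. They therefore cannot show how often the preset correlation gives false calls for lists whose genes vary together.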

Results

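The series measured gene expression in mouse embryonic stem cells that carry a green fluorescent reporter of Oct4 (Pou5f1), the transcription factor that marks the undifferentiated state. Control cells were kept with leukemia inhibitory factor (LIF), the cytokine that holds these cells in self-renewal. The others were grown without LIF for 1, 3 or 5 days, or without LIF but with 0.1 uM retinoic acid (RA) for 1 or 2 days. Cells were sorted by reporter brightness into high, medium and low Oct4 gates. Each of the 18 RNA samples was hybridised to a chip A and a chip B of an Affymetrix mouse genome set, 36 arrays in all. The control arm held 3 RNA samples (2 high and 1 medium gate) and day 1 without LIF held 4 (2 high, 1 medium, 1 low). Days 3 and 5 without LIF and day 1 with RA held 3 each (1 per gate), and day 2 with RA held 2 (medium and low). Most combinations of arm and gate thus had 1 sample, and the gates of an arm served as its replicates. The labels do not say that the samples came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

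The median signal of an array lay between 37.7 and 48.7 on chip A and between 65.5 and 76.3 on chip B, and the number of arrays limits the precision. The run records place the arrays on 4 scan days. Scan 1 held control high replicate 2 and day 1 without LIF high replicate 2. Scan 2 held all day 3 libraries without LIF and all day 1 libraries with RA. Scan 3 held the other 3 day 1 libraries without LIF, all day 5 libraries and both day 2 libraries with RA, and scan 4 held the other 2 controls. Shortened RNA raises the log2 ratio of 3' to 5' signal of Actb. On chip A it averaged 1.22 ± 0.12 (SD, n = 3) in controls and 1.01 ± 0.20 (SD, n = 15) in the other libraries (two-sided exact permutation p = 0.108). On chip B it averaged 1.27 ± 0.14 and 1.02 ± 0.21 (two-sided exact permutation p = 0.0833). For Gapdh the control libraries lay 0.09 higher on chip A (two-sided exact permutation p = 0.548) and 0.14 higher on chip B (two-sided exact permutation p = 0.382). Adjusted over these 4 tests, the smallest p was 0.216 (exact permutation). The day 1 libraries with RA had the highest arm mean for Gapdh on both chips, 1.28 and 1.28, and for Actb on chip A, 1.33.

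The library labelled day 1 without LIF, high gate, replicate 2 (the doubted library) stood apart from the rest of its arm. Among the 40 genes that were higher with RA in both of the comparisons that stay within a scan day (described with the RA results), its mean log2 difference from the scan 4 controls was 1.96, against 0.00338 to 0.0759 in the other 3 day 1 libraries without LIF and 1.92 to 1.96 in the day 1 libraries with RA. Over the 14 genes lower in both it was at -0.98, against -0.13 to -0.0958 in the other day 1 libraries and -1.38 to -1.14 with RA. The other day 1 libraries and the RA libraries served to choose these genes, so their ranges were set apart by that choice. The doubted library took no part in it. Over chip A its mean correlation, across probe sets, was 0.967 with the day 1 RA libraries, 0.960 with day 3 without LIF and 0.943 with the other day 1 libraries without LIF. Over chip B these were 0.932, 0.923 and 0.887. Cyp26a1, the enzyme that breaks down RA, had a log2 signal of 8.87 in it and 3.94 to 4.15 in the other 3. Within scan 3, day 2 with RA was only 2.07 above those 3, so the doubted library lay above that RA level rather than at it. The library was kept under its label in the counts that lead each comparison, and each count is also given without it, a choice made after the data were seen.

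**Figure D1:**
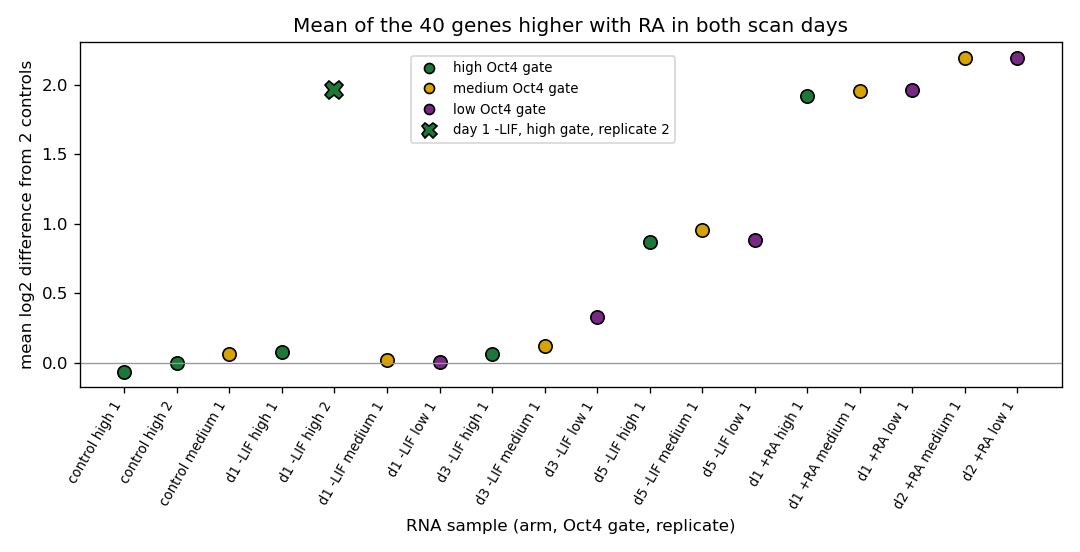
Mean log2 difference from the 2 scan 4 controls (vertical axis) of the 40 genes higher with RA in both scan days, for each of the 18 RNA samples (horizontal axis); each point is 1 sample, coloured by Oct4 gate. The cross, the library labelled day 1 without LIF, high gate, replicate 2, sits at 1.96, while the other day 1 libraries without LIF sit between 0.00338 and 0.0759.

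**Figure D2:**
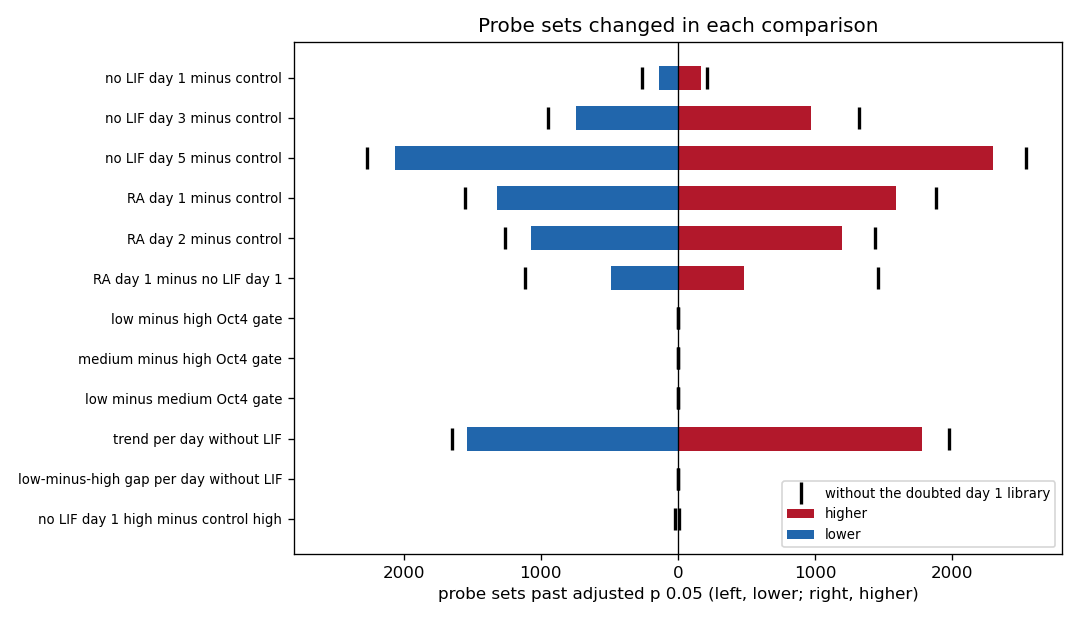
Number of probe sets past adjusted p 0.05 in each of the 12 comparisons (horizontal axis; lower to the left, higher to the right), with bars from all samples and black ticks from the fit without the library labelled day 1 without LIF, high gate, replicate 2. The bars reach 2061 lower and 2299 higher at day 5 without LIF and 0 between the gates.

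The comparison of day 5 without LIF with control asked what the longest time without LIF had changed. Controls with LIF were collected only at 2 days after plating. Longer time in culture and loss of LIF therefore cannot be told apart here, at day 3 or in the slope per day. The pluripotency network, the transcription factors and markers of undifferentiated cells, fell: 18 of its 22 measured members fell and none rose (adjusted over the list alone, 19 fell). Dppa2 fell by 4.15 ± 0.20 on the log2 scale (SE, adjusted p = 3.69e-09, 17.7-fold). Sox2, a partner of Oct4, fell with it (-2.51 ± 0.17), as did Dppa5a (-2.72 ± 0.16) and the TGF-beta family ligand Gdf3 (-2.26 ± 0.18). Pou5f1 itself fell by 1.81 ± 0.33 (adjusted p = 0.00067), together with Nanog (-1.83 ± 0.29), Zfp42 (-3.38 ± 0.37) and Klf4 (-2.23 ± 0.39). The list had a median log2 change of -2.18 and camera's adjusted p = 5.68e-13 (adjusted p = 0.29 with an estimated correlation). Of 14 measured LIF and STAT3 targets and receptors, 2 rose and 6 fell. Socs3, the feedback inhibitor of LIF signalling, fell by 1.49 ± 0.16 and Pim3 fell by 0.73 ± 0.14, while Junb rose by 1.38 ± 0.22 (list adjusted p = 0.0659).

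At day 5 genes of the primitive streak and early mesoderm rose. Of 11 measured members 7 rose and none fell (adjusted over the list alone, 9 rose). Lhx1 was 4.43 ± 0.39 higher (SE, 21.5-fold), Wnt3, a ligand that starts the streak, 4.23 ± 0.39, Pdgfra 3.35 ± 0.40 and Tbx6 1.94 ± 0.18. The list's median was 1.19 with an adjusted p = 0.000105 (adjusted p = 0.262 with an estimated correlation). Of 10 measured trophoblast genes 7 rose, led by the simple-epithelium keratins Krt8 (4.49 ± 0.43) and Krt18 (4.26 ± 0.36). Igf2 (3.41 ± 0.51) and Eomes (3.18 ± 0.44), which is also a streak gene, rose too, and none of these 4 is limited to trophoblast. The trophoblast median was 1.80, adjusted p = 0.00203 (adjusted p = 0.308 with an estimated correlation). Among 19 extraembryonic endoderm genes 8 rose and 3 fell (adjusted over the list alone, 4 fell). The activin inhibitor Fst (4.03 ± 0.42), Col4a2 (1.68 ± 0.24) and Sparc (1.51 ± 0.21) were higher and Amn lower (-1.65 ± 0.25). This list did not pass (adjusted p = 0.229), and Gata6, its endoderm regulator, was at 0.35 ± 0.19 (adjusted p = 0.182).  The other lineage lists did not pass as groups at day 5. Of 10 postimplantation epiblast genes 5 rose and 2 fell, with Sox4 1.96 ± 0.33 (SE), Lef1 1.90 ± 0.29 and Cldn6 1.68 ± 0.26 higher (list adjusted p = 0.189). Of 13 neural progenitor genes 4 rose and 3 fell. N-cadherin (Cdh2), which mesoderm also makes, rose by 4.65 ± 0.39 and Sox11 by 1.48 ± 0.28. Neurod1 fell by 2.08 ± 0.21 and Sox1 was lower too (-0.98 ± 0.32), with a list adjusted p = 0.563. Of 10 Hox genes 2 rose, Hoxb1 (2.59 ± 0.85) and Hoxb2 (1.56 ± 0.47), with a list adjusted p = 0.287. Of 9 RA response genes 1 rose and 2 fell (list adjusted p = 0.752). Cyp26a1 rose by 6.72 ± 0.89 although no RA was added, and the RA receptors Rarg (-1.62 ± 0.25) and Rara (-0.75 ± 0.16) fell. Of 7 blood and endothelium genes 1 rose, Lmo2 (1.30 ± 0.27, list adjusted p = 0.717).

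Markers of fibroblasts, the feeder cells used in routine culture, also rose at day 5. Of 14 measured 10 rose and none fell (adjusted over the list alone, 10 rose and 1 fell). Among them were the smooth muscle and mesenchyme gene Tagln (3.94 ± 0.56, SE), the proteoglycan Dcn (3.41 ± 0.38), Cald1 (2.91 ± 0.41) and Col5a1 (1.68 ± 0.15). The fibroblast list had a median of 1.09 and adjusted p = 0.00145 (adjusted p = 0.301 with an estimated correlation). Genes of dissociation and sorting stress rose in 7 of 14 cases (adjusted over the list alone, 7 rose and 2 fell), with Jun at 2.72 ± 0.43 and Fos at 2.67 ± 0.46 (list adjusted p = 0.0571). The Actb 3' to 5' ratio, set beside all of these groups, averaged 0.86 in day 5 libraries and 1.22 in controls on chip A.  Genes that drive division fell in part at day 5. Of 20 proliferation genes 7 fell and 1 rose, with Mybl2 at -2.21 ± 0.33 (SE), E2f1 at -1.14 ± 0.12 and Rrm2 at -0.70 ± 0.15. The proliferation median was -0.30, adjusted p = 0.00477 (adjusted p = 0.347 with an estimated correlation). Among 10 cyclins D and CDK inhibitors 5 rose and 1 fell, with Ccnd2 2.50 ± 0.59 and the inhibitor Cdkn1c 1.11 ± 0.21 higher (list adjusted p = 0.189). Among 10 p53 targets 6 rose and 1 fell, with Perp, a cell adhesion protein of epithelia, 2.14 ± 0.37 and Phlda3 1.16 ± 0.18 higher (list adjusted p = 0.0636). Of 16 Polycomb and DNA methylation genes 8 fell and 2 rose. Dnmt3l, the cofactor of de novo methylation, fell by 2.23 ± 0.31, and so did Eed, a core subunit of the Polycomb methyltransferase (-1.42 ± 0.22), Phc1 (-1.67 ± 0.28) and Jarid2 (-1.31 ± 0.21). The Polycomb median was -0.61, adjusted p = 0.00815 (adjusted p = 0.29 with an estimated correlation). Of 13 glycolysis genes 3 fell and 1 rose (list adjusted p = 0.121). Pfkp (-3.02 ± 0.27), Hk2 (-1.81 ± 0.11) and Pdk1 (-1.62 ± 0.20), the kinase that restrains pyruvate oxidation, fell and the glucose transporter Slc2a3 (1.09 ± 0.30) rose. For lists with no separate figure in the 4 main comparisons with all samples, here and below, the counts adjusted over the list alone were the same as those given.

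The largest rises and falls are ranked among genes past the brightness filter and the test. At day 5 the largest rises were those of the interferon-induced GTPases Gbp2 (6.96 ± 0.37, SE, 124-fold) and Gbp2b (6.78 ± 0.32). Cyp26a1 and the immunoproteasome subunit Psmb8 (6.19 ± 0.43) followed. After them came the growth factor binding protein Igfbp3 (5.42 ± 0.34), Slit3 (4.85 ± 0.32), Sprr2b (4.78 ± 0.20) and Dach1 (4.71 ± 0.83). The largest falls were those of the oocyte and embryo gene Ooep (-4.30 ± 0.30), Nr0b1 (-4.21 ± 0.63), a nuclear receptor of the pluripotency network, Fam25c (-4.15 ± 0.29) and Dppa2. Next were Trap1a (-4.11 ± 0.21), the microtubule protein Mapt (-4.03 ± 0.61), the Wnt receptor Fzd5 (-3.91 ± 0.37) and Mras (-3.89 ± 0.44). In all, 4360 of 14900 probe sets changed in limma's test (2299 higher and 2061 lower, 3 libraries against 3), which covered 3191 of 9833 genes. The median 95% interval of a log2 change was 0.45 on either side. The count was 4810 without the doubted library.  With scan day as a fixed block 3627 probe sets changed at day 5, where control and day 5 libraries are joined only through the scan 1 pair and so through the doubted library. With scan day as a random block 3658 changed. Within scan 3, day 5 against the 3 day 1 libraries without LIF changed 4592 probe sets (2488 higher and 2104 lower). Of 22 pluripotency genes 19 were lower there (adjusted p = 1.83e-12, 0.426 as an adjusted p with an estimated correlation). Of 11 streak genes 8 were higher (adjusted p = 0.000129, 0.519 as an adjusted p with an estimated correlation), as were 10 of 14 fibroblast markers (adjusted p = 0.000848, 0.556 as an adjusted p with an estimated correlation).

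**Figure D3:**
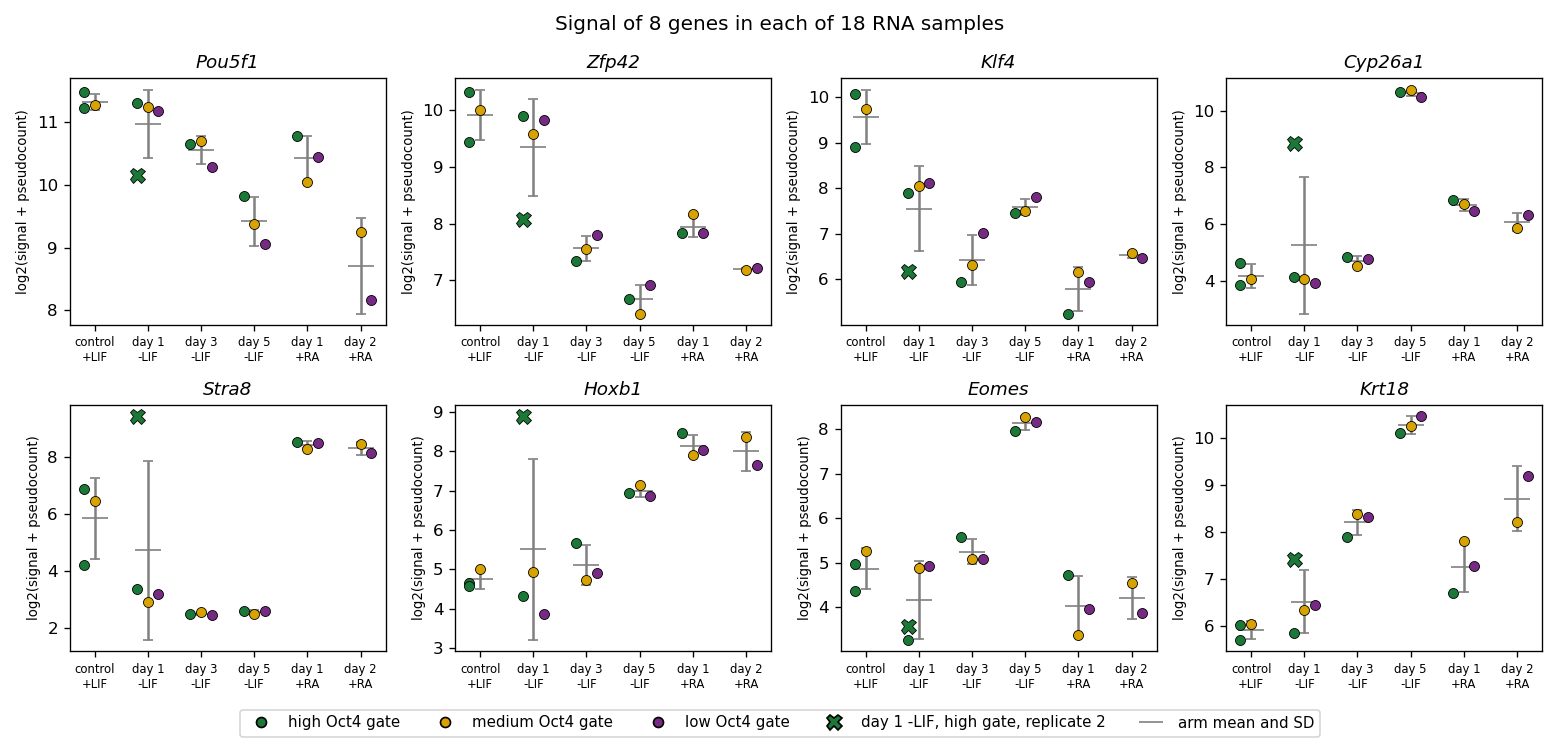
Log2 of signal plus pseudocount (vertical axes) of 8 genes in the 18 RNA samples, grouped by arm (horizontal axes) and coloured by Oct4 gate; bars are the arm mean and SD, and the cross marks the library labelled day 1 without LIF, high gate, replicate 2. In the Cyp26a1 panel that library sits at 8.87 and the other 3 of its arm between 3.94 and 4.15.

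The earlier days asked when these changes began. At day 1 without LIF (4 libraries against 3) Socs3 had fallen by 2.39 ± 0.15 (SE, adjusted p = 1.17e-06). Klf4, a LIF target of the pluripotency network, had fallen by 2.15 ± 0.36 (adjusted p = 0.0066). Pou5f1 was at -0.28 ± 0.30 (adjusted p = 0.699) and Nanog at -0.47 ± 0.27 (adjusted p = 0.396). When the doubted library was left out, Pou5f1 was at 0.08 ± 0.22 (adjusted p = 0.882) and Nanog at -0.14 ± 0.19 (adjusted p = 0.75), while Klf4 (-1.73 ± 0.27) and Socs3 (-2.36 ± 0.16) still fell. At day 3 (3 libraries against 3) Socs3 (-2.71 ± 0.16), Klf4 (-3.39 ± 0.39), Zfp42 (-2.49 ± 0.37) and Nanog (-0.95 ± 0.29) had fallen and Krt18 had risen by 2.18 ± 0.36. Pou5f1 was at -0.68 ± 0.33 then (adjusted p = 0.181). From day 1 to day 5 within scan 3, Socs3 rose by 0.88 ± 0.17 (adjusted p = 0.00705). In limma's test 307 probe sets changed at day 1 (171 higher and 136 lower) and 1716 at day 3 (973 higher and 743 lower). Without the doubted library these counts were 472 and 2264, and with scan day as a random block 72 and 387. A fixed block gave 535 at day 1, again through the doubted library. It could not be estimated at day 3, whose libraries share no scan with a control or another day without LIF.

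Fitted as a slope per day over the 13 libraries of control and days 1, 3 and 5, Zfp42 fell by 0.71 ± 0.08 per day (SE, adjusted p = 8.58e-05). Nanog (-0.36 ± 0.05) and Pou5f1 (-0.36 ± 0.06) fell as well, while Gbp2 rose by 1.42 and Krt18 by 0.88 ± 0.06 per day. Socs3, lowest at day 3, was at -0.16 ± 0.15 per day (adjusted p = 0.48). The slope passed for 3320 probe sets (1782 higher and 1538 lower), and for 3621 without the doubted library. With scan day as a fixed block it passed for 4803 and as a random block for 4518. Among these libraries scan 2 holds only day 3 and scan 4 only controls. The fixed block slope therefore rests on days 1 and 5 in scan 3 and on the scan 1 pair, which includes the doubted library.

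The comparison of day 1 with RA and day 1 without LIF asked what RA added on the same day (3 libraries against 4). Hox cluster genes, the positional regulators that RA activates, were higher. Hoxb1 rose by 2.77 ± 0.78 (SE, adjusted p = 0.0416, 6.80-fold) and Hoxb2 by 1.76 ± 0.42, while Hoxa2 (0.83 ± 0.26) and Hoxb7 (0.83 ± 0.27) did not pass. That made 2 of 10 measured (adjusted over the list alone, 5 rose), with a list median of 0.83 and adjusted p = 0.00879 (adjusted p = 0.381 with an estimated correlation). Of 9 RA response genes 1 rose (adjusted over the list alone, 3 rose and 1 fell): Dhrs3, a retinaldehyde reductase, by 1.66 ± 0.44. Stra8 was at 3.83 ± 1.14 (adjusted p = 0.0537), Crabp1 at 0.66 ± 0.20 (adjusted p = 0.0585) and Cyp26a1 at 1.56 ± 0.81 (adjusted p = 0.252), and the list did not pass (adjusted p = 0.0702). Without the doubted library Stra8 was 5.26 higher (adjusted p = 1.28e-05) and Cyp26a1 2.62 higher (adjusted p = 2.58e-06). There 6 of the 9 rose (list adjusted p = 0.000277, adjusted p = 0.0474 with an estimated correlation).

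In the same comparison 7 of 22 pluripotency genes fell (adjusted over the list alone, 11 fell and 1 rose). Klf4 fell by 1.88 ± 0.35 (SE), and Tcl1, an activator of AKT kinase (-1.74 ± 0.31), Zfp42 (-1.46 ± 0.34) and Fbxo15 (-1.32 ± 0.26) fell with it. Pou5f1 at -0.52 ± 0.30 (adjusted p = 0.299), Nanog at -0.60 ± 0.26 and Sox2 at -0.47 ± 0.15 were not past the test. All 3 passed when the doubted library was left out, at -0.82 (adjusted p = 0.0162), -0.87 (adjusted p = 0.00465) and -0.53 (adjusted p = 0.0242). Adding scan day as a random block left Nanog past the test (adjusted p = 0.038) but not Pou5f1 (adjusted p = 0.0899) or Sox2 (adjusted p = 0.119). The pluripotency median was -0.55, adjusted p = 2.79e-06 (adjusted p = 0.308 with an estimated correlation). Of 13 neural progenitor genes 3 rose (adjusted over the list alone, 7 rose and 1 fell). They were Cdh2 (1.45 ± 0.36), Sox11 (1.01 ± 0.25) and Nes (0.89 ± 0.26), the intermediate filament of neural stem cells. The neural list had an adjusted p = 0.00247 (adjusted p = 0.29 with an estimated correlation).  Fibroblast markers, proliferation genes and Polycomb genes also passed as lists at day 1 with RA. Of 14 fibroblast markers Dcn (2.20 ± 0.34, SE), Tagln (2.03 ± 0.51) and Timp3 (0.75 ± 0.22) rose (adjusted over the list alone, 3 rose and 1 fell). The fibroblast list passed (adjusted p = 0.0479, adjusted p = 0.465 with an estimated correlation), but not after quantile normalization. Of 20 proliferation genes 4 fell (adjusted over the list alone, 6 fell), with Mybl2 at -1.57 ± 0.30 and Mcm7 at -0.69 ± 0.13. The proliferation list had an adjusted p = 0.000492 (adjusted p = 0.29 with an estimated correlation). Of 16 Polycomb and DNA methylation genes 3 fell and 1 rose (adjusted over the list alone, 9 fell and 2 rose), with Eed at -0.75 ± 0.20 and Phc2 at 1.60 ± 0.47. The Polycomb list had an adjusted p = 0.0104 (adjusted p = 0.29 with an estimated correlation). The 3' to 5' ratio beside these groups averaged 1.28 for Gapdh on chip A in the RA libraries and 0.89 in the day 1 libraries without LIF.

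The other lists did not pass at day 1 with RA. Of 14 LIF and STAT3 genes 4 fell and 1 rose (adjusted over the list alone, 6 fell and 2 rose). The homeobox gene Gbx2 was 1.56 ± 0.26 (SE) higher and the LIF receptor Lifr lower (-1.31 ± 0.24, list adjusted p = 0.0935). In the streak list 1 of 11 fell, Bmp4 (-1.15 ± 0.33, list adjusted p = 0.752). In the extraembryonic endoderm list 1 of 19 fell, Apoe (-0.66 ± 0.13, list adjusted p = 0.495). Of 10 epiblast genes none passed (adjusted over the list alone, 2 rose and 2 fell), and the list adjusted p = 0.973. Nor did any of 10 trophoblast genes (list adjusted p = 0.0879) or 7 blood and endothelium genes (list adjusted p = 0.341) pass. Among 10 cyclins D and CDK inhibitors Ccnd2 rose by 2.40 ± 0.53 and Ccnd1 by 0.77 ± 0.17 (list adjusted p = 0.127). Among 14 stress genes Atf3 rose by 1.69 ± 0.33 and Egr1 fell by 0.87 ± 0.19 (list adjusted p = 0.661), and of 10 p53 targets Perp rose by 1.27 ± 0.33 (list adjusted p = 0.0901). Of 13 glycolysis genes Hk1 rose by 0.98 ± 0.18 while Pfkp (-1.25 ± 0.25) and Pdk1 (-0.73 ± 0.18) fell (adjusted over the list alone, 3 fell and 1 rose). The glycolysis list had an adjusted p = 0.533.

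The largest rises and falls with RA at day 1 are ranked among genes past the brightness filter and the test, which leaves out Stra8 (3.83). The rises were led by Prtg (3.53 ± 0.78, SE), a cell surface protein of the early neural plate and mesoderm. The Wnt ligand Wnt8a (3.37 ± 0.63) and the cytokine Il33 (3.32 ± 0.88) were next. Hoxb1, Fgfbp1 (2.57 ± 0.55), Ccnd2, the channel protein Panx1 (2.37 ± 0.20) and Samd4 (2.29 ± 0.48) followed. The largest falls were those of Mapt (-2.21 ± 0.55), Nr0b1 (-2.19 ± 0.57), C730049O14Rik (-1.97 ± 0.35) and Klf4. Calml4 (-1.75 ± 0.38), Tcl1, Hmces (-1.73 ± 0.24) and Rhox5 (-1.72 ± 0.31) came after them. In limma's test 972 of 14900 probe sets changed (483 higher and 489 lower), 662 of 9833 genes. The count was 2571 without the doubted library (1457 higher and 1114 lower). With scan day as a random block 4 passed, or 1291 without the doubted library. A fixed block could not be estimated because no scan held both arms.

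Because RA and day 1 arms lay on different scan days, RA was also set against cells without LIF and RA inside each scan day, at unequal days. Within scan 2, day 1 with RA against day 3 without LIF, Stra8, a germ cell gene that RA induces, was 5.92 ± 0.14 higher (SE, adjusted p = 4.45e-05), Hoxb1 3.03 ± 0.14, Gbx2 4.13 ± 0.14 and Cyp26a1 1.96 ± 0.15. Within scan 3, day 2 with RA against day 1 without LIF, Stra8 was 5.19 ± 0.18 higher (adjusted p = 4.8e-05), Hoxb1 3.60 ± 0.20, Gbx2 1.52 ± 0.19 and Cyp26a1 2.07 ± 0.19. The RA response list was higher in both (adjusted p = 0.000129 and 0.000176, adjusted p = 0.466 and 0.426 with an estimated correlation), as was the Hox list (adjusted p = 0.00257 and 0.000391, adjusted p = 0.519 and 0.556 with an estimated correlation). These comparisons share no library and called 245 and 1863 probe sets. At gene level 85 and 801 genes were higher and 40 were shared, against 6.92 for independent lists among 9833 genes (Fisher's exact p = 9.12e-22), and 84 and 609 were lower and 14 were shared, against 5.2 (Fisher's exact p = 0.000591). Another 14 genes were called in opposite directions. RNA quality differed between the scan 2 arms as well: the Gapdh 3' to 5' ratio on chip A averaged 1.28 with RA and 0.70 at day 3 without LIF. For the scan 3 comparison it averaged 0.73 at day 2 with RA and 0.89 over all day 1 libraries without LIF, the doubted library included.

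The comparison of day 2 with RA and control asked what the longest RA exposure, together with loss of LIF, had changed (2 libraries against 3, without a high gate). Controls kept LIF and no arm held day 2 without LIF alone, so RA and loss of LIF cannot be told apart here. Klf4 and Socs3, for example, had also fallen at day 1 without LIF, as given above. Day 1 with RA against control holds the loss of LIF as well. Hox genes rose in 6 of 10 cases: Hoxb2 by 3.36 ± 0.54 (SE, 10.3-fold), Hoxb5 by 2.85 ± 0.72 and Hoxb6 by 2.23 ± 0.46. The Hox median was 1.53, adjusted p = 0.00203 (adjusted p = 0.308 with an estimated correlation). Of 9 RA response genes 3 rose and 2 fell (adjusted over the list alone, 4 rose and 2 fell). The retinoic acid binding proteins Crabp2 (3.58 ± 0.83) and Crabp1 (2.60 ± 0.26) and Dhrs3 (2.01 ± 0.56) rose, and Rarg (-1.16 ± 0.29) fell. The RA response list did not pass (adjusted p = 0.175), and Cyp26a1 was at 2.46 ± 1.04 (adjusted p = 0.117). Of 22 pluripotency genes 18 fell and 1 rose (adjusted over the list alone, 20 fell and 1 rose). Klf4 (-3.51 ± 0.45), Zfp42 (-2.95 ± 0.43), Pou5f1 (-2.47 ± 0.38), Fbxo15 (-2.42 ± 0.33) and Nr5a2 (-2.34 ± 0.34) fell, as did Nanog (-1.36 ± 0.34), Sox2 (-1.01 ± 0.19) and Nr0b1, given below. The member that rose was the Nodal inhibitor Lefty1, named after the values were seen. The pluripotency median was -1.70, adjusted p = 6.01e-12 (adjusted p = 0.29 with an estimated correlation). Of 14 LIF and STAT3 genes 6 fell and 3 rose (adjusted over the list alone, 8 fell and 3 rose), with Bcl3 at -2.30 ± 0.44, Socs3 at -2.27 ± 0.19 and Ier3 at -0.99 ± 0.22. The LIF and STAT3 list passed (adjusted p = 0.0308, adjusted p = 0.29 with an estimated correlation).

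Other groups moved at day 2 with RA. Of 13 neural progenitor genes 5 rose and 1 fell (adjusted over the list alone, 6 rose and 1 fell). Cdh2 (4.40 ± 0.46, SE), the early neural factor Sox3 (2.18 ± 0.38) and Ncam1 (1.67 ± 0.18) rose and Neurod1 (-1.52 ± 0.25) fell. The neural list had an adjusted p = 0.00477 (adjusted p = 0.301 with an estimated correlation). Of 10 epiblast genes 4 rose, among them Sall2 (3.35 ± 0.43), Sox4 (2.48 ± 0.39) and Pou3f1 (1.72 ± 0.36), with a list adjusted p = 0.00935 (adjusted p = 0.29 with an estimated correlation). The epiblast list did not pass with scan day as a fixed block (2 rose and 2 fell, adjusted p = 0.499), nor did it within scan 3 against day 1 without LIF (2 rose and 3 fell, adjusted p = 0.788). Of 19 extraembryonic endoderm genes 9 rose and 1 fell. Dab2, an endocytic adaptor of endoderm, was 3.64 ± 0.58 higher, Fst 3.09 ± 0.49 and Col4a1 2.37 ± 0.40 (list adjusted p = 0.00203, adjusted p = 0.301 with an estimated correlation). Of 10 trophoblast genes 4 rose (adjusted over the list alone, 5 rose and 1 fell), among them Igf2 (3.09 ± 0.60), Krt18 (2.60 ± 0.42) and Krt8 (2.46 ± 0.50). The trophoblast list had an adjusted p = 0.0395 (adjusted p = 0.465 with an estimated correlation).  Fibroblast markers rose in 6 of 14 cases at day 2 with RA and 1 fell (adjusted over the list alone, 7 rose and 1 fell), with Tagln at 4.79 ± 0.65 (SE), Dcn at 4.03 ± 0.44 and Acta2 at 3.33 ± 0.52. The fibroblast list had an adjusted p = 0.000649 (adjusted p = 0.29 with an estimated correlation). Of 20 proliferation genes 3 fell, Mybl2 (-2.20 ± 0.39), E2f1 (-0.99 ± 0.14) and Rrm2 (-0.59 ± 0.18), with a list adjusted p = 0.00223 (adjusted p = 0.308 with an estimated correlation). The Actb 3' to 5' ratio beside these groups averaged 0.83 on chip A, against 1.22 in controls.

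The remaining lists did not pass at day 2 with RA. Of 11 streak genes Wnt3 rose, by 2.49 ± 0.46 (SE, list adjusted p = 0.661), and none of 7 blood and endothelium genes (list adjusted p = 0.77) or 10 p53 targets (list adjusted p = 0.533) passed. Among cyclins D and CDK inhibitors 3 of 10 rose (adjusted over the list alone, 4 rose), with Ccnd2 at 3.24 ± 0.69 and Cdkn1c at 1.30 ± 0.25 (list adjusted p = 0.0626). Of 16 Polycomb and DNA methylation genes 5 fell and 2 rose (adjusted over the list alone, 8 fell and 3 rose). Jarid2 was at -1.40 ± 0.25, Eed at -1.25 ± 0.25 and Phc2 at 2.95 ± 0.60 (list adjusted p = 0.0571). Of 14 stress genes 3 rose and 1 fell, with Atf3 at 2.33 ± 0.42 and Jun at 1.97 ± 0.50 (list adjusted p = 0.341). Of 13 glycolysis genes 3 fell and 1 rose (adjusted over the list alone, 3 fell and 2 rose). Pfkp was at -3.45 ± 0.32, Pdk1 at -1.34 ± 0.23 and Slc2a1 at 1.60 ± 0.40 (list adjusted p = 0.516).

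Among genes past the brightness filter and the test, Dach1 rose most at day 2 with RA (5.59 ± 0.97, SE, 48.1-fold). The myelin protein gene Pmp22 (5.13 ± 0.90), the imprinted zinc finger gene Plagl1 (4.98 ± 0.82) and Prtg (4.95 ± 1.01) were next. Tagln, the Wnt secretion factor Wls (4.55 ± 0.64), Wnt8a (4.48 ± 0.80) and Eml1 (4.48 ± 0.40) came after them. The largest falls were those of Cpt1a (-4.87 ± 0.67), which carries fatty acids into mitochondria, Nr0b1 (-4.54 ± 0.74), Ppm1j (-3.99 ± 0.46) and Mapt (-3.69 ± 0.71). Cobl (-3.69 ± 0.79), Lrrc2 (-3.63 ± 0.68), Klf4 and Calml4 (-3.46 ± 0.48) followed. In limma's test 2267 probe sets changed (1199 higher and 1068 lower), 1690 genes, and 2694 without the doubted library. With scan day as a fixed block, which again runs through the doubted library, 2674 changed, and as a random block 2240. Within scan 3, against day 1 without LIF, 1863 changed (1081 higher and 782 lower), and the RA response list passed there, as given above. Day 1 with RA against control (3 libraries against 3) changed 2908 probe sets (1590 higher and 1318 lower), with Klf4 at -4.03 ± 0.39, Socs3 at -2.66 ± 0.16 and Hoxb1 at 3.74. That count was 3431 without the doubted library, and with scan day as a random block 942.

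**Figure D4:**
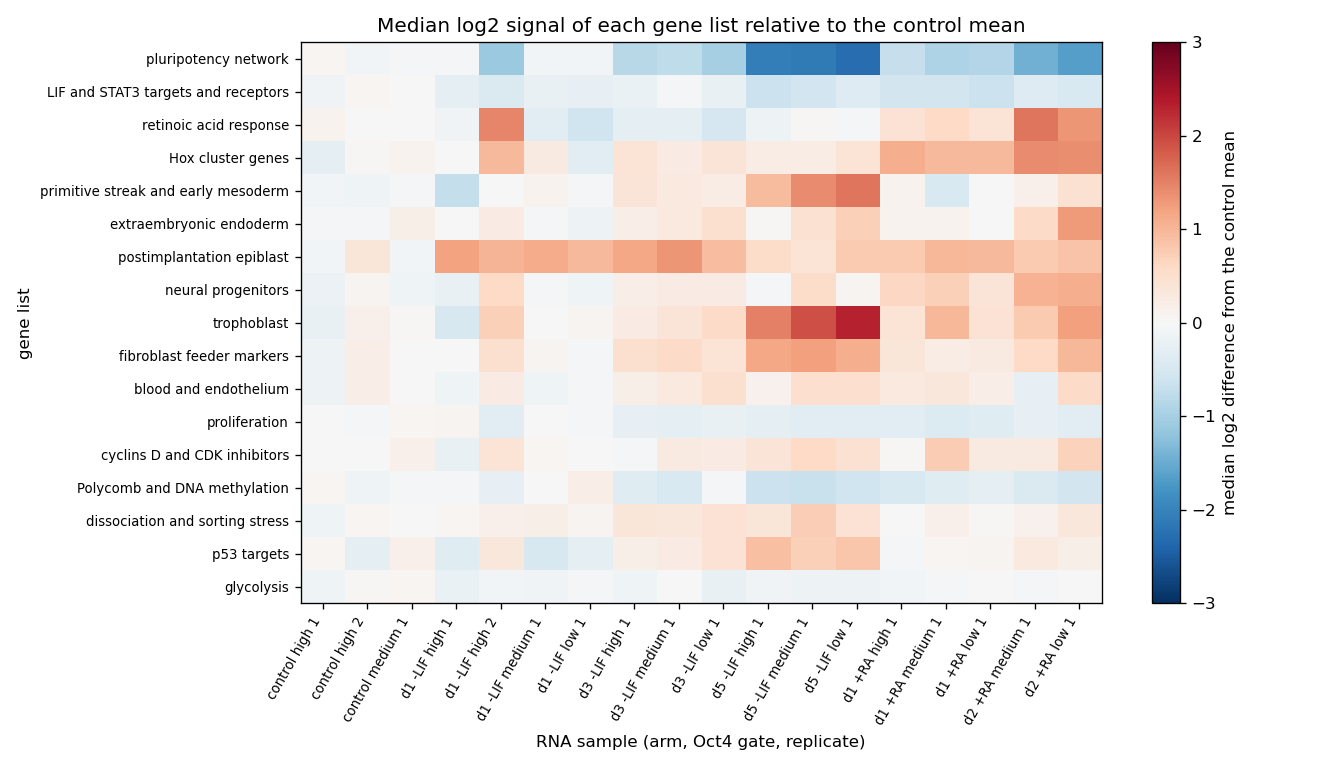
Median log2 difference from the control mean (colour, from -3 to 3) over the measured members of each of the 17 gene lists (vertical axis) in each of the 18 RNA samples (horizontal axis). The pluripotency list sits at -1.12 in the library labelled day 1 without LIF, high gate, replicate 2, and between -0.0865 and -0.0346 in the other day 1 libraries without LIF.

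Low and high Oct4 gates were compared to see which genes went with reporter level inside an arm (5 low and 7 high libraries). Both gates were present only at days 1, 3 and 5 without LIF and at day 1 with RA. Control had no low gate and day 2 with RA no high gate. Pou5f1, the gene behind the reporter, was at -0.28 ± 0.25 in the low gate (SE; 95% interval -0.81 to 0.24, adjusted p = 0.935), and at -0.47 ± 0.17 without the doubted library (95% interval -0.85 to -0.10, adjusted p = 0.569). Low minus high was -0.36 at day 3 without LIF, -0.77 at day 5, -0.32 at day 1 with RA and 0.46 at day 1 without LIF, where it was -0.12 without the doubted library. The sort used this gene's reporter, so the value checks the labels only. Of the other pluripotency genes, Sox2 was at 0.07 ± 0.13 in the low gate, Nanog at 0.18 ± 0.22, Zfp42 at 0.39 ± 0.28, Klf4 at 0.75 ± 0.29 and Dppa3 at 0.82 ± 0.28 (list median 0.13, adjusted p = 0.0844). Leaving out the doubted library, which is in the high gate, gave 0.03, 0.01, 0.16, 0.52 and 0.78 for these 5 genes and a list median of -0.01 (adjusted p = 0.338), as did a fixed scan block for the list (adjusted p = 0.305). No gene passed in limma's test, in any list or among all 14900 probe sets, where 808 had an unadjusted p under 0.05 against 745 by chance, and the median 95% interval was 0.34 on either side.

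As a group, extraembryonic endoderm genes were shifted higher in the low gate (median 0.24, adjusted p = 0.000267, adjusted p = 0.29 with an estimated correlation). Cubn, an endocytic receptor of visceral endoderm, was at 1.41 ± 0.37 (SE), Amn, its partner, at 0.82 ± 0.19, Col4a2 at 0.56 ± 0.18 and Gata4 at -0.56 ± 0.19. None was past the test (adjusted over the list alone, 3 rose). Trophoblast genes were shifted the same way (median 0.27, adjusted p = 0.0308, adjusted p = 0.446 with an estimated correlation), with Igf2 at 0.68 ± 0.39 and Tfap2c at 0.54 ± 0.24. Both shifts also passed without the doubted library (adjusted p = 3.5e-05 and 4.31e-05, adjusted p = 0.118 for both with an estimated correlation). Within scan 2 and scan 3 the endoderm list had an adjusted p of 0.0103 and 0.00257, and the trophoblast list 0.0234 and 8.35e-05. With an estimated correlation these 4 lay between an adjusted p of 0.426 and 0.615. LIF and STAT3 genes were shifted higher (median 0.13, adjusted p = 0.0395, adjusted p = 0.29 with an estimated correlation). Adjusted over the list alone, Socs3 rose there (0.43 ± 0.12). RA response genes were shifted lower (median -0.28, adjusted p = 0.0308, adjusted p = 0.441 with an estimated correlation). Without the doubted library neither of these passed (adjusted p = 0.0533 and 0.15).

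The other lists did not pass between the gates. Their adjusted p was 0.0659 for Hox genes, 0.447 for streak genes, 0.621 for epiblast genes, 0.278 for neural progenitors, 0.672 for fibroblast markers and 0.154 for blood and endothelium. It was 0.875 for proliferation, 0.341 for cyclins D and CDK inhibitors, 0.234 for Polycomb and DNA methylation, 0.341 for stress, 0.229 for p53 targets and 0.965 for glycolysis. Among their members Pdgfra was at 1.09 ± 0.30 (SE) and Cdkn2b at 0.72 ± 0.21 (adjusted over the list alone, 1 streak gene and 1 of the CDK inhibitors rose), and the fibroblast marker Acta2 was at 0.69 ± 0.34. Medium against high and low against medium gates also gave 0 probe sets in limma's test (715 and 453 at an unadjusted p under 0.05). Without the doubted library the low against high count stayed at 0 (1042 at an unadjusted p under 0.05). With scan day as a fixed block (1234), as a random block (944), within scan 2 (842) and within scan 3 (952) limma's count was also 0, with the number at an unadjusted p under 0.05 in brackets.

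Whether the gates moved apart with days without LIF was tested as the low gate's slope minus the high gate's slope over 13 libraries. No probe set passed in limma's test (388 at an unadjusted p under 0.05), but in simulated data this test recovered 0 of 100 probe sets with a 2-fold and 7 of 100 with a 4-fold effect. The high gate alone at day 1 without LIF against control high (2 libraries against 2) also gave 0 (768 at an unadjusted p under 0.05), with 0 of 100 and 38 of 100 simulated 2-fold and 4-fold changes recovered, and 31 passed without the doubted library (10 higher and 21 lower), where the lone day 1 sample left is assumed to vary like the 2 controls.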

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

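All tests of explanations in this part, and the comparison with other splits of the samples, were chosen after the results were seen.

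In the day 1 arm without LIF 5 of 30 quantities had 1 library far from the other 3 by Dixon's ratio (gap over range, above its 95% critical value for 4 samples), against 1.5 by chance. The quantities come from the same 4 libraries and some overlap, as Pou5f1 and Klf4 are in the pluripotency list, so the 5 are not independent. In all 5 the library apart was the one labelled day 1 without LIF, high gate, replicate 2. They were the median of the pluripotency list (Dixon ratio 0.952; -1.12 against -0.0865 to -0.0346), Cyp26a1 (0.956; log2 signal 8.87 against 3.94 to 4.15), Pou5f1 (0.896; 10.15 against 11.18 to 11.30), Klf4 (0.892; 6.18 against 7.90 to 8.10) and the Gapdh 3' to 5' ratio on chip B (0.841; 0.70 against 1.12 to 1.20).

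The pattern in that library is that genes raised by RA are high in it, and the 14 genes lowered by RA are low (-0.98, against -0.13 to -0.0958 in the other day 1 libraries and -1.38 to -1.14 with RA). Its shared scan day with control high replicate 2 is argued against by that control, whose mean over the 40 RA-raised genes lies 0.000431 from the other controls. Of the 40 genes 25 stand above all 9 other libraries without LIF, days 3 and 5 included. The genes were chosen as lower at days 1 and 3 without LIF than with RA, so those libraries were low by selection. The day 5 libraries were not set against RA in that choice, and their means over the 40 genes were 0.87 to 0.956, against 1.96. Faster differentiation without RA is thus argued against as the whole cause only by the day 5 libraries. Over chip A the library also resembles day 3 without LIF (mean correlation 0.960, against 0.967 with day 1 RA). Over these genes the library lies 101% of the way from the other day 1 libraries without LIF to those with RA, so a wrong label or exposure to RA may account for it, and the tests here do not separate those 2. The library does not match day 1 with RA throughout. Its RA response list median is 1.46 above control, against 0.40 to 0.59 at day 1 with RA and 1.32 to 1.61 at day 2. The scores cannot tell whether labels were swapped inside the series. The lowest RA library scores 1.92, but the genes were chosen for being higher in the RA libraries. Day 2 with RA also has no high gate library.

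The second pattern is that no probe set passed limma's test between the low and high gates (808 at an unadjusted p under 0.05). A spread too wide to see 2-fold differences shared by the arms is argued against for most probe sets, since 93.8% of the 95% intervals lie inside a 2-fold difference. These intervals are for a gate difference averaged over arms, so a difference limited to some arms or days is not covered. The test for a gap that changes with days recovered 0 of 100 simulated 2-fold effects. The doubted library in the high gate is not the cause of the count, which stays at 0 without it (1042 at an unadjusted p under 0.05). That the sorted gates held cells of similar Pou5f1 level may still apply: Pou5f1 was at -0.28 in the low gate, with a 95% interval of -0.81 to 0.24 that holds both no difference and a fall of over 1.5-fold. Without the doubted library it was at -0.47 (95% interval -0.85 to -0.10) and with a fixed scan block at -0.49, so a difference is seen there while its size stays open. No biological explanation was tested.

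The third pattern is that Cyp26a1, an RA-induced gene, rose at day 5 without added RA, by 6.57 ± 0.16 from day 1 within scan 3, against 2.07 ± 0.19 after 2 days of RA. RA carried into the day 5 cultures could raise it: of the other 39 RA-raised genes 17 reached at least 50% of their change with RA, while Stra8 changed by -0.59 (95% interval -0.95 to -0.22) at day 5 against 5.19 with RA, which leaves the question open. A median over those genes was computed before this count and set aside after it was seen (0.43 at day 5 against 1.93 with RA, or 22%). Of the 39 genes 19 rose past the test at day 5 and 9 fell. The changes at day 5 and with RA start from the same day 1 libraries, which by itself makes them more alike. Cyp26a1 may instead belong to a primitive streak programme, as the streak list's median rose by 1.63 over the same days (8 of 11 genes rose, adjusted p = 0.000129, adjusted p = 0.519 with an estimated correlation), but 2 things that rise together do not show a link. These 2 explanations cannot be told apart here for Cyp26a1, because no sample isolates RA signalling or the streak cells at day 5. The day 1 libraries from which Cyp26a1 rose lay at a log2 signal of only 3.94 to 4.15, and detection calls were not analysed. The sizes of its changes within scan 3 therefore depend on the pseudocount.

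For day 1 without LIF against control no other split reached the real count. There 1 of 35 splits (the real one) gave as many as 307 probe sets, and the next gave 175. For the slope per day 1 of 100 splits reached 3320 and the next 247. At day 1 this is the smallest share that 35 splits can give, unadjusted over the comparisons, and leaving out control medium lowers the count to 44. The labels do not say that the libraries came from separate cultures, so chance between cultures is not excluded. These splits ignore scan day, which is not excluded: at day 1 the count is 72 with scan day as a random block, and 1 with only the samples compared. The splits are too few for a share under 0.05 at day 3 without LIF (1 of 10 splits; 1716 against at most 1), day 5 without LIF (1 of 10; 4360 against 0), day 1 with RA against control (1 of 10; 2908 against 1), day 5 against day 1 within scan 3 (1 of 10; 4592 against 0) and day 1 with RA against day 3 without LIF within scan 2 (1 of 10; 245 against 0). For day 1 with RA against day 1 without LIF 2 of 35 splits gave 972 or more, so chance is not excluded. The other split gave 2599 and places the doubted library with the 3 RA libraries, which points to a structure of the samples. Any split reaches a count of 0, so for the gates this test says nothing about chance: limma's counts of 0 were reached by 100 of 100 splits (low against high, at most 8; medium against high, at most 2; low against medium, at most 1; 808, 715 and 453 at an unadjusted p under 0.05 in the real split). The same holds for the difference in slope (0 against at most 569 in 100 of 100 splits, 388 at an unadjusted p under 0.05).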

How the results depend on the processing

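Scan day as a random block, leaving out the doubted library, both together, the within-scan fits and the left-out fits of the lists and RNA quality were chosen after the data were seen. The number of arrays limits the precision, and where no cause is given the cause was not tested.

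Of 331 named gene changes, 325 of the 330 tested kept direction and side of the threshold with 0.1 of the pseudocount, 323 of 327 with 4 times it, 304 without a filter, 320 of 327 after quantile normalization and 326 with a trended, robust variance. With only the samples compared 252 did, with scan day as a random block 279, without the doubted library 301, and with a fixed scan block 220 of 245, where Stra8 at day 5 reversed to 4.61. That fixed block joins controls to scan 3 only through the doubted library. It could not be fitted for day 3 without LIF, day 1 with RA or the high gate pair at day 1, and the random block was not run for that pair because its correlation could not be estimated.

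With no filter the count was 101 at day 1 without LIF, 380 at day 1 with RA against day 1 without LIF, and 1 each for medium against high and low against medium gates. A fixed scan block gave 535 at day 1 without LIF. With only the samples compared, and so fewer samples, the counts were 1, 324 and 2585 at days 1, 3 and 5 without LIF, 900 and 465 at days 1 and 2 with RA, and 5 for day 1 with RA against day 1 without LIF. The random block gave 72 and 387 at days 1 and 3 without LIF, 942 at day 1 with RA and 4 for day 1 with RA against day 1 without LIF. Dropping the doubted library gave 472 at day 1 without LIF, 2571 for day 1 with RA against day 1 without LIF and 31 for the high gate pair, and both together gave 55 at day 1 without LIF. A trended, robust variance gave 1 for the high gate pair. Quantile normalization left 2107 higher and 2306 lower at day 5, against 2299 and 2061, and 1540 higher and 1725 lower for the slope, against 1782 and 1538, so the side with more probe sets changed. It also changed among the brightest 30% at day 5 (1389 and 1603), for the slope (1051 and 1282) and at day 2 with RA (904 and 919, against 1199 and 1068). Of the 25 list calls, 0 of 68 camera tests passed with an estimated correlation. After quantile normalization 61 of 68 list results were the same, 2 calls were lost (fibroblast markers at day 1 with RA, LIF and STAT3 genes between the gates) and 2 were gained (stress and p53 targets at day 5). With a fixed scan block 34 of 51 were the same, 9 were gained and 2 were lost (epiblast genes at day 2 with RA, RA response genes between the gates).

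The replicate numbers gave 2 groups of 2 whose deviations correlate at 0.173 on chip A and 0.115 on chip B, and the labels give the number no meaning. The replicate 2 libraries share scan 1, while the replicate 1 libraries lie on scans 4 and 3. With the replicate block the count was 685 at day 1 without LIF, against 307, and 0 in limma's test of the high gate pair, as without it (768 at an unadjusted p under 0.05).

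With each library left out in turn the counts ran from 44 to 472 at day 1 without LIF, 871 to 2264 at day 3, 3132 to 4810 at day 5, 1686 to 3431 at day 1 with RA, 852 to 2694 at day 2 with RA, 149 to 2571 for day 1 with RA against day 1 without LIF, 0 to 1 for low against high gate, 0 to 0 for the other gates and the difference in slope, 1899 to 3621 for the slope and 0 to 387 for the high gate pair. The Pou5f1 gate value ran from -0.48 to -0.17, the list calls from 20 to 32, and the 3' to 5' differences from 0.04 to 0.15 (Gapdh, chip A), 0.08 to 0.23 (Gapdh, chip B), 0.15 to 0.27 (Actb, chip A) and 0.17 to 0.29 (Actb, chip B). Without RA day 1 high the Actb differences were 0.24 (exact permutation p = 0.0368) and 0.28 (exact permutation p = 0.0235).

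Counts that moved by over 1.5 times were, at day 1 without LIF, 45 without control high 1, 44 without control medium, 472 without the doubted library, 87 and 112 without day 1 medium and low, 199 and 196 without day 3 high and low, 184 and 177 without day 5 medium and low, 204, 196 and 193 without day 1 RA high, medium and low, and 193 without either day 2 RA library. At day 3 they were 899 and 955 without control high 1 and control medium, and 871 and 918 without day 3 high and medium. At day 1 with RA against control they were 1686 without control medium and 1925 and 1738 without RA high and medium. At day 2 with RA they were 1449 without control medium and 852 and 866 without RA medium and low, where the lone sample left is assumed to vary like the other groups. For day 1 with RA against day 1 without LIF they were 313, 218 and 211 without day 1 high 1, medium and low, 2571 without the doubted library, and 280, 201 and 149 without RA high, medium and low. The slope gave 1992 and 1899 without day 5 high and medium, low against high gate 1 without day 1 medium, and the high gate pair 387 and 31 without day 1 high 1 and 2, where again 1 sample is left.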

Other observations

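All gene groups in this part were put together after the gene changes were seen, so they are not independent evidence of direction, and their adjusted p covers these groups only. At day 5 without LIF, genes of the interferon response and of antigen processing rose: 16 of 20 measured rose and 1 fell (median 2.48, adjusted p = 5.29e-09, adjusted p = 0.0697 with an estimated correlation). Beside Gbp2 and Psmb8 they include B2m (3.76), which carries class I molecules to the surface, the class I genes H2-D1 (1.72) and H2-K1 (1.33), the peptide transporter Tap1 (2.47), the immunoproteasome subunits Psmb9 (2.49) and Psmb10 (2.50), and the regulator Irf1 (2.55), while Irf8 was at -1.02. Within scan 3, from day 1 to day 5, 15 of the 20 rose and none fell (adjusted over the list alone, 16 rose and 1 fell). There camera gave an adjusted p = 6.62e-09 (adjusted p = 0.238 with an estimated correlation). At day 2 with RA 11 rose against control (adjusted p = 7.28e-05, adjusted p = 0.143 with an estimated correlation). Germ line and oocyte genes fell at day 5: 8 of 13 fell (adjusted over the list alone, 9 fell and 1 rose), among them Trap1a (-4.11), Khdc3 (-3.88), Rhox5 (-3.16), Tex19.1 (-2.81) and the egg coat gene Zp3 (-2.57), with a median of -2.63 and adjusted p = 1.79e-06 (adjusted p = 0.0227 with an estimated correlation).

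Epithelial and mesenchymal genes rose together at day 5, 12 of 17 with 1 fall (adjusted p = 1.28e-05, adjusted p = 0.127 with an estimated correlation). Keratin Krt19 (4.18) and the tight junction genes Cldn7 (1.62) and Cldn3 (1.35) rose, and so did the mesenchymal regulators Twist1 (2.44) and Snai2 (0.96) and N-cadherin Cdh2 (4.65), while Epcam was at -0.47 and E-cadherin Cdh1 at 0.14 (adjusted p = 0.634). Of 16 Wnt pathway genes 6 rose and 2 fell (adjusted p = 0.0218, adjusted p = 0.173 with an estimated correlation): Wnt6 (4.43), Fzd2 (3.24) and Wnt5b (2.33) rose and Fzd5 (-3.91) and Sfrp1 (-1.34) fell. Imprinted genes rose at day 2 with RA, 7 of 17 with 1 fall (adjusted over the list alone, 8 rose), among them Plagl1 (4.98), the fetal growth genes Mest (3.48) and Igf2 (3.09), Ndn (2.40), Sgce (1.98) and Magel2 (1.82), with an adjusted p = 0.000315 (adjusted p = 0.158 with an estimated correlation). At day 5 without LIF 7 of the 17 rose (adjusted p = 0.0134, adjusted p = 0.283 with an estimated correlation).

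Some list members too dim for the filter passed when no filter was used, and values this dim depend on the pseudocount. Of 71 such members 15 rose and 2 fell (Foxd3 -1.72, Tek -0.83) at day 5 without LIF, and 11 rose and 2 fell (Foxd3 -2.36, Tbx3 -1.59) at day 2 with RA. With RA at day 1 against day 1 without LIF 3 rose. At day 5 without LIF those higher included the streak genes Fgf8 (6.23), Gsc (4.13), Mesp1 (3.89) and Snai1 (3.46) and the epiblast gene Fgf5 (1.95). At day 2 with RA they included the RA response genes Meis1 (3.58), Stra6 (2.31) and Meis2 (2.16), Hoxa7 (2.73) and the neural gene Zic1 (3.59).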
